A study of Homo sapiens with 24 samples.

How the data were processed

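The series measured RNA levels in human embryonic stem cell lines on 24 Affymetrix U133 Plus 2.0 arrays, each hybridised with biotin-labelled total RNA. Per the labels' protocols, RNA was isolated with a column kit from Stratagene and labelled with an Ambion kit. The authors deposited 1 table of log2 values for 54675 probe sets, and per the submitters' processing notes these log2 values came from RMA, a method that corrects background, brings the arrays to a common distribution and summarises the probes of each set. The version of that software, and whether all arrays were processed together, are not given in the sources used here. The values ran from 2.05 to 14.9 with no missing value, and the array medians ran from 6.09 to 6.35. Arrays carry no read depth, and their number limits the precision.

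Samples were assigned to groups from their titles. The inhibitor part holds 12 arrays, 1 for each of the lines H1, H9 and HSF1 in each of 4 conditions: feeder-supported (FS) or feeder-free (FF) culture, with DMSO or with 250 nM AZD3965, an inhibitor of the lactate transporter MCT1, for 5 days. The medium part holds 12 feeder-free arrays, 3 biological replicates each of H9 and HSF1 cells in unconditioned medium or in medium conditioned by mouse embryonic fibroblasts (MEFs). The labels give 5 days for conditioned medium and the series' design text gives 24 hours, so the duration of that treatment stays open here. In the inhibitor part a replicate number stands for a cell line, so numbers pair the samples, and the line was a block in the fit. In the medium part the numbers did not pair the samples and no block was used. The p-values of that part measure the spread between biological replicates of the same line. They do not measure how far lines respond alike, and the part holds 2 lines. For the inhibitor part the labels name 1 array per line and condition, so those p-values measure how far lines respond alike over all 4 conditions. The block holds the line but not the pair of DMSO and inhibitor arrays within a culture system. The spread used for inhibitor effects therefore includes how differently the lines respond to feeders.

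Probe sets were named from the platform annotation supplied with the data: 41097 carried 1 gene symbol, 1801 several and 11777 none. Of the first group, 41043 matched the gene table by Entrez identifier, and 0 symbols needed an update. Each gene was represented by the probe set with the highest mean over all 24 arrays among those naming 1 gene, which gave 19775 genes. Genes above a log2 value of 5 on at least 3 of the 12 arrays of a part were tested, 17218 in the inhibitor part and 16572 in the medium part. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with all 12 arrays of a part sharing 1 estimate of the spread, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Adjusted p-values below come from limma unless a list is named. Differences are on the log2 scale, given with the standard error (SE) of the fit.

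The comparisons used 26 gene lists of 538 genes: general, primed-state and naive-state pluripotency; mesoderm and primitive streak, endoderm, neuroectoderm, and trophoblast and amnion; glycolysis, lactate and pyruvate handling, hypoxia response, TCA cycle, oxidative phosphorylation, pentose phosphate and serine pathway, amino acid and integrated stress response, unfolded protein response, cholesterol synthesis, and fatty acid synthesis and desaturation; targets of Nodal and TGF-beta, BMP, FGF and ERK, WNT and p53; cell cycle; fibroblast markers; metallothioneins; and interferon response. Lists were tested with limma's camera, which compares the genes of a list with all other genes, at a preset inter-gene correlation of 0.01 and, as an alternative, at an estimated correlation, adjusted over the 26 lists of a comparison. Of the list genes 48 have no probe set of their own in the annotation used, among them the inhibitor's target, which is not analysed here. The groups, the fits of the comparisons, the lists, the naming rule and most alternatives were chosen before the data were examined. The fits without arrays that stand apart, the ACTB covariate, and the list tests without a line or with another block were added after the data were seen. The rule names, for each of 3 main comparisons, the 8 genes with the largest rise and the 8 with the largest fall among genes past the threshold that moved the same way in every line or pair, up to 4 members of each list with the smallest p, the 4 genes with the smallest p in each direction of an interaction, and 7 genes in any case.

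Correlations of effects were computed across genes, which are not independent replicates. For effects fitted on the same arrays, 100 simulated data sets without any effect gave a range of correlations. This range was narrower than the spread between lines, so a value outside it was not read as an association. List medians were also set against 10000 random lists matched on the level in feeder-free inhibitor arrays. The alternatives were other low-value filters, the mean of a gene's probe sets, 2 other scalings, other variance models, array weights, other sets of arrays in the fit, fits with and without the block, and leaving out each line or array, together with those added later. The fits were tested on simulated data with 200 changed genes per comparison. At a true log2 difference of 1, 25.4% of changed genes were recovered for the culture system, 74.3% for the mean inhibitor effect, 2.9% for the inhibitor interaction and 100% for the mean conditioned medium effect. Where far more genes change, as between culture systems (6772 past the threshold), the adjustment is less strict. The simulated share of 25.4% is therefore not the recovery in that comparison. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.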

Results

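RNA levels were profiled in 3 human embryonic stem cell lines, H1, H9 and HSF1, to ask how feeder cells, medium conditioned by feeder cells and a block of lactate transport alter gene expression. Feeder-supported cultures grow on mouse embryonic fibroblasts and feeder-free cultures grow without them. AZD3965 inhibits MCT1, a transporter that carries lactate across the plasma membrane, and was given at 250 nM for 5 days with DMSO as the control. Each of the 4 combinations of culture system and treatment had 1 array per line, 12 arrays in all. A further 12 arrays compared conditioned with unconditioned medium in feeder-free H9 and HSF1 cells, with 3 biological replicates per group. The number of arrays limits the precision.

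The feeder-supported HSF1 arrays stood apart. Both correlated with the other 22 arrays at r = 0.860 to 0.961, against 0.948 to 0.998 among those 22, and their interquartile range was 2.45 against 2.66 to 3.30. On the first principal component, which held 60.3% of the variance, these arrays scored 124 and 134, the other feeder-supported arrays 35 to 62, and all feeder-free arrays -39.7 to -8.35. The 3-prime minus 5-prime difference of the ACTB control probe sets, a sign of RNA degradation, was 3.25 and 2.89 in replicates 2 and 3 of H9 in unconditioned medium, against 1.07 in replicate 1 and 1.42 to 1.84 in H9 in conditioned medium.

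**Figure D1:**
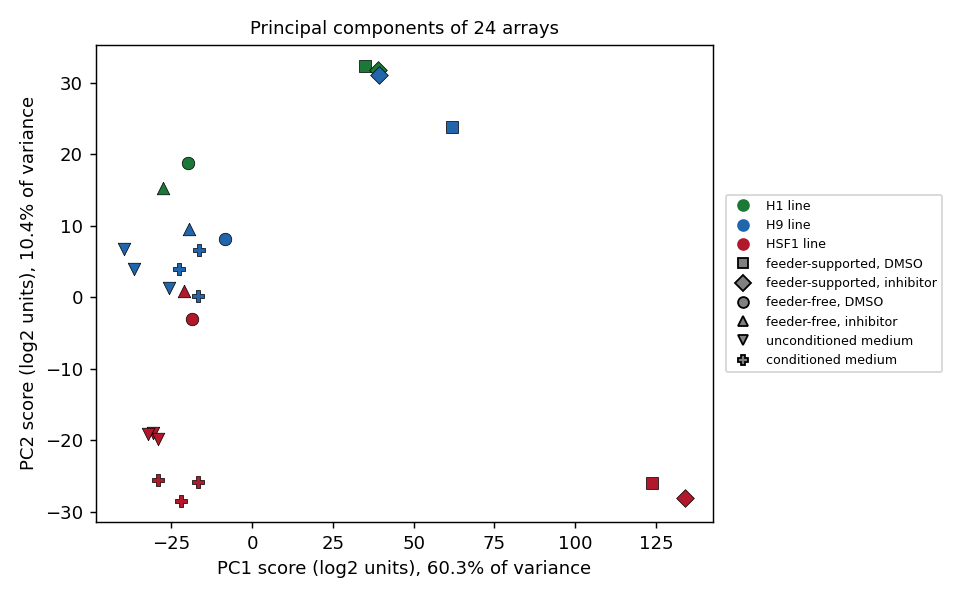
Scores of the 24 arrays on the first and second principal components (log2 units), with colour for the cell line and shape for the condition. Feeder-supported arrays lie to the right of all feeder-free arrays, and both feeder-supported HSF1 arrays lie furthest to the right, at 124 and 134.

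With DMSO, arrays of feeder-supported cultures showed lower levels of genes of cholesterol and fatty acid synthesis and higher levels of fibroblast markers and naive-state genes than feeder-free arrays of the same line. The calls of these 4 lists were lost with an estimated correlation (adjusted p = 0.451, 0.288, 0.211 and 0.121). RNA of the mouse feeder cells could not be told apart from a response of the human cells. HOXC6, a homeobox gene of body-axis patterning, was higher by 6.73 on the log2 scale (SE 0.429, adjusted p = 7.9e-06, 3 of 3 lines), at 12.4 ± 0.599 with feeders and 5.64 ± 0.19 without (SD, n = 3 each). The other largest rises were those of TSHZ1 (5.66), ZFHX3 (5.26), CDH11 (4.70), a cadherin of mesenchymal cells, S100A6 (4.57), PCDH7 (4.50), ANXA1 (4.47) and CPEB2 (4.42). These 7 values come from 1 probe set of several per gene, and with the mean of all probe sets they were 3.45, 1.92, 1.38, 2.44, 1.05, 2.61 and 1.86, each past the threshold. The largest falls were those of CUZD1 (-3.44, SE 0.474, adjusted p = 0.00136), FABP7 (-3.40), a fatty acid binding protein of neural progenitors, GDA (-3.39), FGFBP3 (-3.02), PLA2G3 (-2.90), SLC38A4 (-2.78), INSIG1 (-2.72) and RORB (-2.67), each in 3 of 3 lines. With the mean of all probe sets GDA, SLC38A4 and RORB fell by 1.82, 1.43 and 1.18. The feeder-free levels of HOXC6 and TSHZ1 (3.36) and the feeder-supported levels of GDA (4.29), SLC38A4 (3.80) and RORB (5.09) lay below the array medians of 6.09 to 6.35, where background limits the value, so these differences give no exact fold. In all, 6772 of 17218 genes passed the threshold, 2620 higher and 4152 lower, of which 331 and 1615 changed at least 2-fold. After quantile normalization 3125 passed, and 50.6% of them were higher against 38.7% as deposited. The median difference over all genes was -0.189 as deposited, -0.305 with arrays shifted to a common median and 0.04 after quantile normalization.

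Lipid synthesis genes were lower on feeders. Of 19 cholesterol synthesis genes 17 fell and 0 rose (camera adjusted p = 8.23e-06; adjusted p = 0.451 with an estimated correlation), and the list median was -0.79, -1.77 and -1.59 in H1, H9 and HSF1. Among them were INSIG1, a regulator of sterol synthesis, and the enzymes FDPS (-1.44, SE 0.207), HMGCS1 (-1.61, SE 0.277) and LSS (-1.79, SE 0.306). Of 14 fatty acid synthesis and desaturation genes 12 fell and 1 rose (adjusted p = 0.000434; adjusted p = 0.288 with an estimated correlation), including FASN (-2.15, SE 0.318) and the desaturase SCD (-1.20, SE 0.154). Of 21 glycolysis genes 11 fell (adjusted p = 0.0102; adjusted p = 0.713 with an estimated correlation), with a list median of -0.20, -0.45 and -0.79 in H1, H9 and HSF1. HK2, a hexokinase, fell by 1.12 (SE 0.281, adjusted p = 0.0156) and ALDOC by 1.49 (SE 0.243), whereas LDHA, the lactate dehydrogenase A gene, differed by -0.33 (SE 0.155, adjusted p = 0.0961) and did not pass, with -0.10 without HSF1 and 0.02 with the ACTB covariate. Of 15 pentose phosphate and serine pathway genes 7 fell (adjusted p = 0.0268; adjusted p = 0.713 with an estimated correlation), a call that ended without the HSF1 arrays (0.0876) or the H9 arrays (0.0505). Of 30 cell cycle genes 13 fell (adjusted p = 0.000242; adjusted p = 0.711 with an estimated correlation), among them MCM5 (-1.03, SE 0.207). The TCA cycle list (6 of 18 genes lower, adjusted p = 0.103) and the list of lactate and pyruvate handling (1 higher and 4 lower of 14, adjusted p = 0.222) did not pass. After quantile normalization the median over all 3 lines moved from -0.58 to -0.20 for cell cycle, from -0.45 to -0.26 for glycolysis, from -0.51 to -0.27 for the pentose phosphate and serine pathway, from -0.44 to -0.05 for the TCA cycle and from -0.46 to -0.06 for lactate and pyruvate handling.

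Genes of signalling and cell state moved in both directions. LEFTY1 (3.42, SE 0.292), NODAL (2.32, SE 0.320) and CER1 (3.34, SE 0.821), a Nodal ligand and extracellular inhibitors of this pathway, rose, although the list of Nodal and TGF-beta targets as a whole did not pass (adjusted p = 0.129). Of 17 naive-state genes 9 rose and 1 fell (adjusted p = 0.000242; adjusted p = 0.121 with an estimated correlation), including KLF5 (2.01, SE 0.234) and NLRP7 (1.87, SE 0.379). Of 19 primed-state genes 13 fell and 2 rose (adjusted p = 0.00452; adjusted p = 0.521 with an estimated correlation), with a median of -0.98 that was -0.60 after quantile normalization. DUSP6, a phosphatase that restrains ERK, fell by 1.33 (SE 0.245), and VIM, the gene of the intermediate filament vimentin, rose by 2.06 (SE 0.241). The lists of endoderm (10 higher and 1 lower of 17), mesoderm and primitive streak (6 higher and 1 lower of 21) and trophoblast and amnion genes (5 higher of 15) rose, with adjusted p = 0.000242, 0.000242 and 0.00558, and with adjusted p = 0.211, 0.288 and 0.210 with an estimated correlation. Examples are PRDM1 (1.07, SE 0.193), EOMES (2.64, SE 0.698) and GATA3 (2.01, SE 0.456). WNT targets rose as a list (5 of 14 higher, adjusted p = 0.0268; adjusted p = 0.288 with an estimated correlation), but not without the H9 arrays (0.0962). SOX2 fell by 0.53 (SE 0.138, adjusted p = 0.0175) and NANOG differed by 0.14 (SE 0.161, adjusted p = 0.460), and 12 of 25 general pluripotency genes fell and 1 rose (list adjusted p = 0.129). In the neuroectoderm list ZIC1 rose by 3.67 (SE 0.317) and ZNF521 fell by 2.66 (SE 0.177), and the list did not pass (adjusted p = 0.225). For neuroectoderm, hypoxia response, p53 targets and the integrated stress response the median, mean and test differed in sign, with adjusted p = 0.225, 0.852, 0.976 and 0.956.

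Fibroblast markers moved with the culture system. Of 31 genes 14 rose and 0 fell (adjusted p = 1.2e-05; adjusted p = 0.211 with an estimated correlation), and the list median was 0.55, 0.81 and 0.45 in H1, H9 and HSF1. TWIST1 rose by 3.74 (SE 0.403) and IGFBP7 by 2.96 (SE 0.277). SPARC, an abundant matrix gene, had log2 values of 11.3 ± 0.741 with feeders and 11.2 ± 0.373 without (SD, n = 3 each). The signal of the human Alu control probe set differed by -0.127 between culture systems (both treatments, SD 0.192 over 3 lines). The 3-prime minus 5-prime difference of ACTB differed by -0.443 (SD 0.346) and that of GAPDH by -0.0545 (SD 0.136). The Alu difference was -0.313 with DMSO and -0.384 with the inhibitor in HSF1, and -0.101 to 0.0287 in H1 and H9. With the ACTB difference as a covariate 351 genes passed between culture systems. Probe sets of a gene disagreed in direction for CDH11 (3 of 4 with the gene's direction), PCDH7 (3 of 5), FABP7 (2 of 3), FASN (1 of 2), SOX2 (3 of 4) and ZIC1 (2 of 3). With the mean of all probe sets FASN was at -0.72, LSS at -1.04, ZIC1 at 1.36, NODAL at 1.47, GATA3 at 1.33 and EGR1 at 1.21.

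The count for the culture system was 1021 without H1, 358 without H9 and 8257 without the feeder-supported HSF1 arrays, and 1836 without the line as a block. Leaving out H1 ended the calls of HK2, SOX2, CER1, EOMES, GATA3, DUSP6 and MCM5 (adjusted p = 0.052 to 0.0906), and leaving out H9 those of FGFBP3, HK2, SOX2, FDPS, LSS, ALDOC, NLRP7, EOMES, PRDM1, GATA3 and MCM5 (adjusted p = 0.0567 to 0.104).

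Under MCT1 inhibition, taken as the mean of both culture systems, BST2, an interferon-induced membrane protein known as tetherin, rose most. It was 6.18-fold higher over both culture systems (log2 2.63, SE 0.174, adjusted p = 8.53e-05), in 6 of 6 pairs of the same line and culture system, and passed in feeder-supported (2.39, SE 0.246) and feeder-free cells (2.87, SE 0.246). CTCFL, the germline relative of the chromatin factor CTCF, rose by 2.01 (SE 0.199) and LGALS1, the galectin-1 gene, by 1.92 (SE 0.308). NTS (1.60), CLIC6 (1.53), ASMTL (1.41), CTHRC1 (1.38) and NID2 (1.34) also rose, but NTS lost its call in 9 of 15 alternatives (adjusted p up to 0.728) and CTHRC1 in 6 of 15 (up to 0.687). PDE4B, a phosphodiesterase that degrades cyclic AMP, fell by 2.14 (SE 0.192, adjusted p = 0.000794), and the homeobox genes OTX2 and HESX1 fell by 1.33 (SE 0.244) and 1.16 (SE 0.127). SEMA6D (-1.28, 4 of 5 probe sets), PLCL2 (-1.18), LINC01844 (-1.13), TNFRSF11A (-1.12) and ABCA5 (-1.11) also fell, but SEMA6D lost its call in 8 of 15 alternatives (adjusted p up to 0.520), among them the mean of its probe sets (-0.40), and TNFRSF11A in 6 of 15 (up to 0.687). With the mean of all probe sets PDE4B fell by 1.08 and CLIC6 rose by 0.99. Of the genes named here, the call ended without H1 for all but BST2 and CTCFL and without H9 for all but BST2 and PDE4B.

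For the mean of both culture systems 110 genes passed, 81 higher and 29 lower, and 90 of them moved the same way in 6 of 6 pairs. After quantile normalization 62.0% of the genes past the threshold were higher, against 73.6% as deposited. In feeder-free cells alone 145 genes passed (104 higher, 41 lower), and in feeder-supported cells BST2 passed alone, against 286 genes at an unadjusted p under 0.05. Without H1 2 genes passed for the mean effect, without H9 2 and without HSF1 500, and without the line as a block 33 passed. The corresponding counts in feeder-free cells were 9, 3 and 421, and 62 without the block. In feeder-supported cells 0 genes passed in limma without any 1 line or without the block, with 114, 96, 1089 and 132 at an unadjusted p under 0.05. BST2 kept its call for the mean effect in all 15 alternatives, whereas without H1 or without H9 the adjusted p of LGALS1 was 0.0659 and 0.520 (2.55e-06 to 0.520 over its 15 alternatives) and that of OTX2 was 0.483 and 0.519 (4.05e-06 to 0.519). Without the feeder-supported HSF1 arrays 1372 genes passed for the mean effect and 1683 in feeder-free cells.

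**Figure D2:**
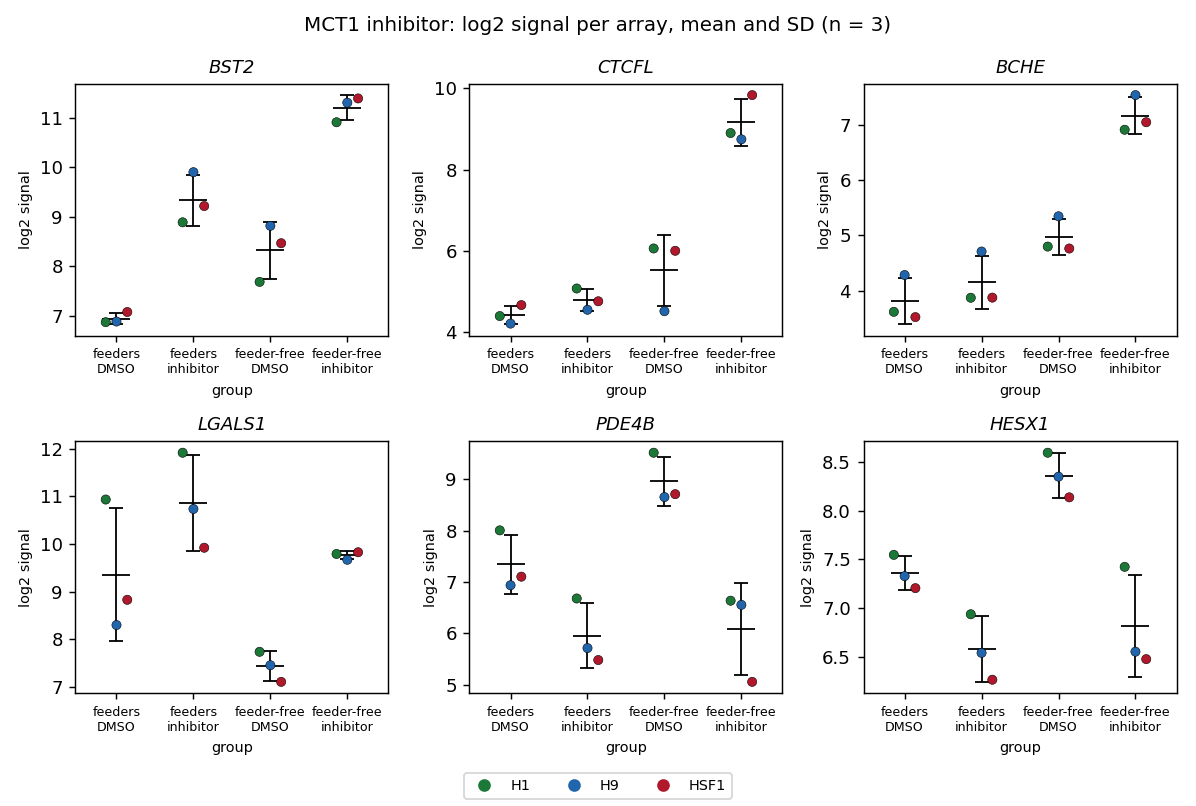
Log2 signal of 6 genes on each array of the inhibitor part, by group, with the mean and SD of 3 lines. BST2 is higher with the inhibitor in both culture systems (log2 2.39 and 2.87), CTCFL and BCHE rise in feeder-free cells (3.64 and 2.20), LGALS1 rises over both systems (1.92), and PDE4B (-2.14) and HESX1 (-1.16) fall.

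Interferon response genes rose as a list (camera adjusted p = 8.06e-06), and this call held with an estimated correlation (adjusted p = 0.0364). The list median was 0.22, 0.25 and 0.16 in the feeder-supported pairs of H1, H9 and HSF1 and 0.23, 0.52 and 0.22 in the feeder-free pairs. Of 20 members 1 passed over all genes, PSMB9, a subunit of the immunoproteasome (0.92, SE 0.135, adjusted p = 0.0145), and 3 adjusted over the list alone. B2M, the light chain of class I molecules, differed by 0.94 (SE 0.202, adjusted p = 0.0685) and IFIT1 by 0.91 (SE 0.200, adjusted p = 0.0737), both in 6 of 6 pairs. The call of PSMB9 ended without H1 (0.429) and without H9 (0.522), within a range of 8.64e-07 to 0.522 over its alternatives. Feeder-supported and feeder-free pairs tested apart passed with the preset correlation (5.31e-05 and 4.5e-05), with adjusted p = 0.0563 and 0.0656 with an estimated correlation.

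Oxidative phosphorylation and hypoxia response genes rose as lists by small amounts. Of 45 oxidative phosphorylation genes 38 had a difference above 0 and 0 passed in limma alone (list median 0.15, adjusted p = 2.86e-05; adjusted p = 0.924 with an estimated correlation). Of 22 hypoxia response genes 0 passed over all genes and 5 adjusted over the list alone (median 0.22, adjusted p = 0.00106; adjusted p = 0.806 with an estimated correlation). PDK1, a kinase that inhibits pyruvate dehydrogenase, was at 0.80 (SE 0.173, adjusted p = 0.0712) and BNIP3 at 1.00 (SE 0.273, adjusted p = 0.188). PDK1 was at 0.36 with the mean of its probe sets and 0.42 with array weights, and its adjusted p ran from 0.000984 to 1 over its alternatives. Over the same contrast LDHA differed by -0.08 (SE 0.110), HK2 by -0.41 (SE 0.199, 0 of 6 pairs higher, adjusted p = 0.669; -0.17 with the mean of its probe sets), SOX2 by -0.16 (SE 0.0978) and NANOG by 0.13 (SE 0.114), none of which passed. The glycolysis list did not pass, and its median, mean and test differed in sign. Fibroblast markers rose (2 of 31 passed, LGALS1 and FBLN2; adjusted p = 5.32e-05; adjusted p = 0.507 with an estimated correlation), but not without HSF1 (0.0511), whose feeder-free pair had a median of 0.60 against 0.07 in H1 and 0.10 in H9. FGF and ERK targets (adjusted p = 0.025) and WNT targets (0.0284) rose and cell cycle genes (0.0274) fell, each with 0 members passing in limma. With an estimated correlation these had adjusted p = 0.806, 0.507 and 0.926, and without HSF1 they had 0.0511, 0.221 and 0.278. The cholesterol synthesis list fell (adjusted p = 0.0276; adjusted p = 0.926 with an estimated correlation), with a median of -0.95 in the feeder-free H9 pair against 0.12 in H1 and -0.09 in HSF1, and the adjusted p was 0.857 without H9 and 0.0511 without HSF1.

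**Figure D3:**
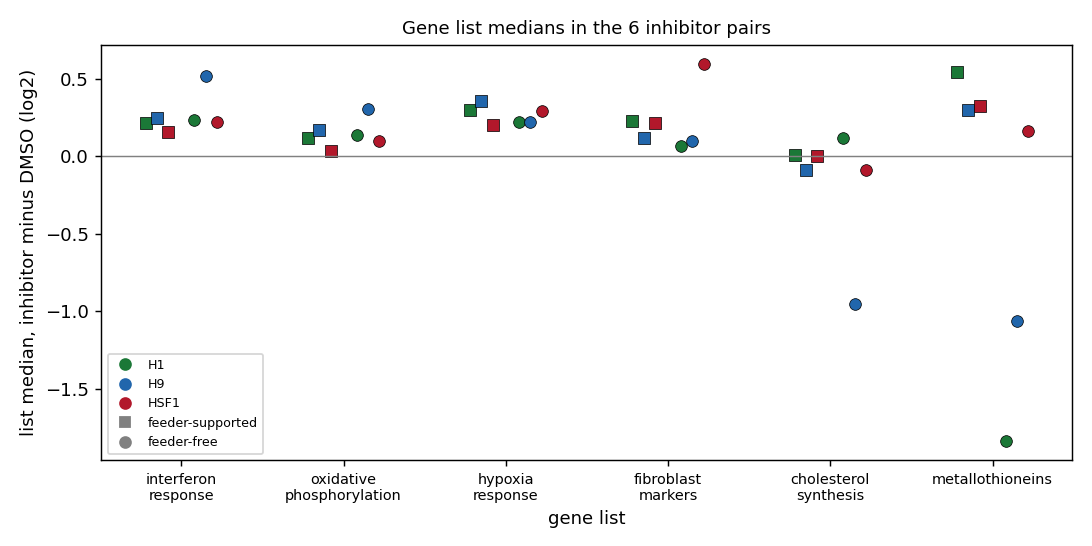
Median log2 difference, inhibitor minus DMSO, of 6 gene lists in each of the 6 pairs (1 symbol per pair, colour for the line, squares feeder-supported, circles feeder-free). The interferon medians lie between 0.16 and 0.52 in all 6 pairs, whereas the metallothionein median is -1.84 and -1.06 in feeder-free H1 and H9 and above 0 in the other pairs.

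The response to the inhibitor differed between culture systems for 3 genes. BCHE, the butyrylcholinesterase gene, rose by 2.20 in feeder-free cells against a difference of 0.34 on feeders (interaction -1.85, SE 0.213, adjusted p = 0.0287). CTCFL rose by 3.64 against 0.37 (interaction -3.27, SE 0.397, adjusted p = 0.0287) and LINC01234 by 2.40 against 0.27 (interaction -2.14, SE 0.279, adjusted p = 0.0387). With the mean of its probe sets LINC01234 rose by 1.35 in feeder-free cells and its interaction was -1.19 (adjusted p = 0.586). The interaction call was lost in 6 of 14 alternatives for BCHE, 9 of 15 for CTCFL and 7 of 14 for LINC01234, with adjusted p up to 1. On feeders the mean levels of these genes were 3.81 to 4.79 with either treatment, below the filter of 5. Background limits the value there, so the differences on feeders and the interactions give no exact size. KCNK12, CCL26, PPP1R17, TM4SF18 and ALDH1A1 had the next smallest p-values and did not pass (adjusted p = 0.141 to 0.266). Metallothioneins, which bind metal ions, differed as a list (median of the interaction 1.41, camera adjusted p = 3.79e-15; adjusted p = 0.353 with an estimated correlation), with 6 of 7 members passing adjusted over the list alone. Their medians with the inhibitor were 0.54, 0.30 and 0.32 on feeders and -1.84, -1.06 and 0.17 without feeders, in H1, H9 and HSF1. Over both culture systems this list fell (adjusted p = 0.00636; adjusted p = 0.806 with an estimated correlation) but not without H1 (0.637) or H9 (0.106), and MT1M differed by -1.17 (SE 0.235, adjusted p = 0.0524). The interaction count was 0 in limma without any 1 line (139, 149 and 789 genes at an unadjusted p under 0.05 without H1, H9 and HSF1) and 0 without the block (207), against 357 in the full fit.

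Conditioned medium raised targets of Nodal, BMP and WNT signalling and metallothioneins and lowered targets of ERK signalling in feeder-free cells. With an estimated correlation the Nodal, BMP and WNT calls held, and those of the metallothioneins and ERK targets were lost (adjusted p = 0.0607 each). Over both lines the largest rises were those of MACC1-OT1 (2.44, SE 0.0717, adjusted p = 1.86e-12), CAV1 (2.04), the gene of the membrane protein caveolin, INSM1 (2.04), LINC00458 (1.98), MT1M (1.89), TFAP2A (1.86), LEFTY1 (1.64) and STOX2 (1.62). The largest falls were those of LRAT (-2.20, SE 0.0706, adjusted p = 5.04e-12), an enzyme that esterifies retinol, CUZD1 (-2.03), the chemokine CXCL5 (-1.70), CHGA (-1.68), DUSP6 (-1.67), APOBEC3B (-1.64), KCNJ2 (-1.61) and TEX14 (-1.59). In all 3982 of 16572 genes passed, 1303 higher and 2679 lower, of which 39 and 40 changed at least 2-fold. After quantile normalization 43.0% of the genes past the threshold were higher, against 32.7% as deposited. With the mean of all probe sets INSM1 was at 1.19, TFAP2A at 0.75, MT1G at 0.81, NODAL at 0.65, SMAD6 at 0.32, FGF4 at 0.67, TFAP2C at 0.76, ETV5 at -0.65, HERPUD1 at -0.20, B2M at -0.18 and SOX2 at 0.48, each past the threshold.

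The ligand-target lists changed as follows. Of 12 Nodal and TGF-beta targets 8 rose and 0 fell (camera adjusted p = 7.81e-08; adjusted p = 0.0172 with an estimated correlation), including NODAL (1.04, SE 0.0622) and FST (1.10, SE 0.0628), which encodes the activin inhibitor follistatin. Of 12 BMP targets 7 rose and 1 fell (adjusted p = 1.71e-06; adjusted p = 0.01 with an estimated correlation), including ID1 (1.58, SE 0.127) and SMAD6 (0.90, SE 0.0662, 3 of 4 probe sets in that direction). Of 11 WNT targets 5 rose (adjusted p = 0.000314; adjusted p = 0.0205 with an estimated correlation). Of 19 FGF and ERK targets 14 fell and 0 rose (adjusted p = 3.88e-11; adjusted p = 0.0607 with an estimated correlation), among them ETV5 (-1.38, SE 0.0562), SPRY4 (-1.27, SE 0.053) and EGR1 (-1.56, SE 0.0771). All 7 metallothioneins rose (adjusted p = 1.02e-12; adjusted p = 0.0607 with an estimated correlation), with MT1G at 1.54 (SE 0.0777).

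Among cell-state lists, 9 of 16 naive-state genes rose and 1 fell (adjusted p = 5.09e-06; adjusted p = 0.01 with an estimated correlation), with FGF4 (1.25, SE 0.0702), KLF4 (1.05, SE 0.0809) and TFAP2C (1.17, SE 0.0881). Of 19 primed-state genes 9 fell, SFRP2 among them (-0.66, SE 0.0443), and 4 rose (adjusted p = 0.0132; adjusted p = 0.148 with an estimated correlation). Endoderm genes (6 of 14 higher, HHEX at 1.15, SE 0.140) and mesoderm genes (7 higher and 2 lower of 19) rose with adjusted p = 0.00118 and 0.022, and with adjusted p = 0.0646 and 0.184 with an estimated correlation. SOX2 and NANOG rose by 0.28 (SE 0.0377) and 0.30 (SE 0.0488), and the general pluripotency list did not pass (adjusted p = 0.117). Of 25 genes of the integrated stress response 14 fell and 3 rose (adjusted p = 0.00175; adjusted p = 0.0784 with an estimated correlation), of 16 unfolded protein response genes 6 fell (0.022; adjusted p = 0.114 with an estimated correlation), with HERPUD1 at -0.60 (SE 0.0628, 1 of 2 probe sets in that direction), and of 30 cell cycle genes 6 fell and 1 rose (0.022; adjusted p = 0.512 with an estimated correlation). The cell cycle call ended without replicates 2 and 3 of H9 in unconditioned medium (0.304). LDHA rose by 0.19 (SE 0.0419, adjusted p = 0.00374), and HK2 differed by 0.10 (SE 0.0467, adjusted p = 0.141), with 1 of its 3 probe sets in that direction. Glycolysis (7 higher and 2 lower of 21, adjusted p = 0.0932) and cholesterol synthesis (2 higher of 19, adjusted p = 0.0916) did not pass. Fibroblast markers did not pass either (6 higher and 7 lower of 27, adjusted p = 0.686), and their median, mean and test differed in sign. FAS, which encodes a death receptor, fell by 1.45 (SE 0.0888), PSMB9 by 0.66 (SE 0.0775) and B2M by 0.33 (SE 0.0444). With all 24 arrays in 1 fit the calls of LDHA, NANOG, HERPUD1 and B2M ended (adjusted p = 0.305, 0.0572, 0.121 and 0.327).

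**Figure D4:**
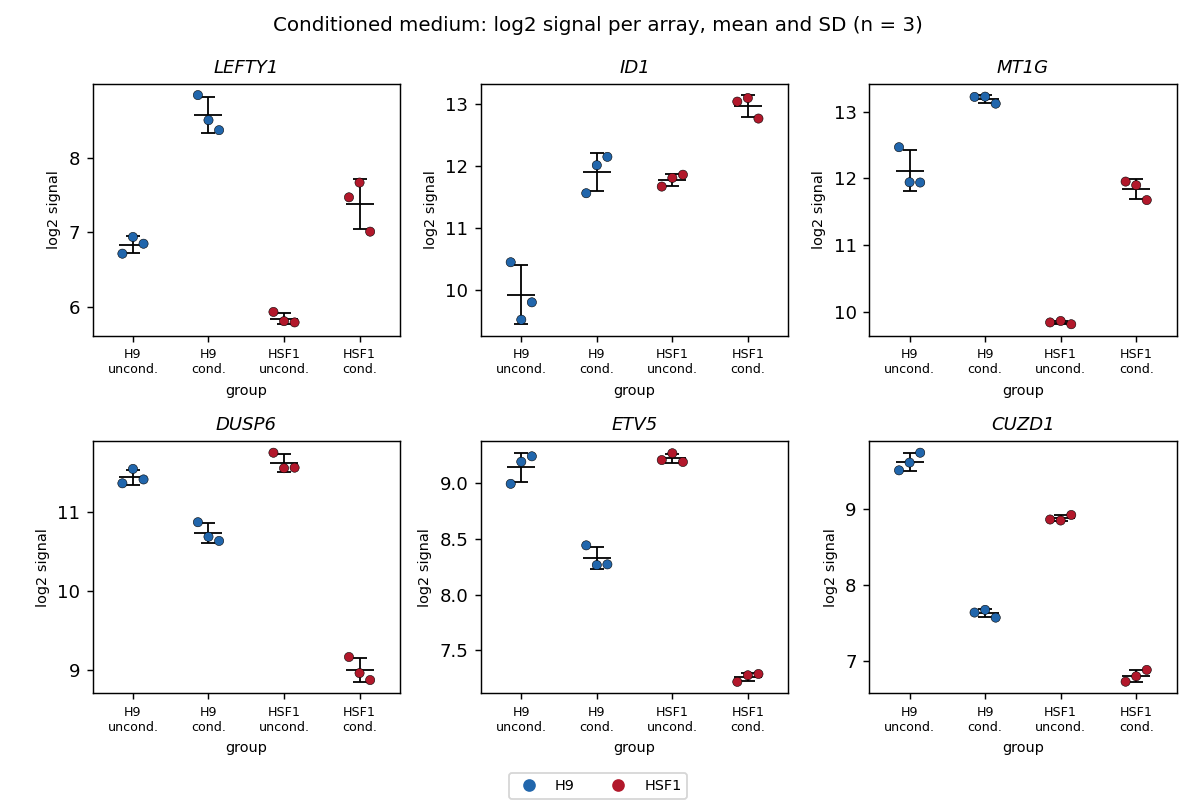
Log2 signal of 6 genes on each array of the medium part, with the mean and SD of 3 replicates per group. LEFTY1, ID1 and MT1G are higher in conditioned medium (1.64, 1.58 and 1.54 over both lines), DUSP6 and ETV5 are lower and fall further in HSF1 (-2.62 and -1.95) than in H9 (-0.71 and -0.81), and CUZD1 is lower (-2.03).

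Within lines, 2720 genes passed in H9, 572 higher and 2148 lower, and 3040 in HSF1, 1420 higher and 1620 lower. The H9 count was 653 without replicates 2 and 3 of H9 in unconditioned medium. It was 5286 without replicate 1 of that group, 1773 and 1320 without its replicates 2 and 3, and 1794 and 1632 without replicates 2 and 3 in conditioned medium, and the HSF1 count was 1852 and 1996 without replicates 1 and 3 in unconditioned medium and 1981 without replicate 3 in conditioned medium. The lines responded differently for 1281 genes. This count was 3281 and 731 without replicates 1 and 3 of H9 in unconditioned medium, 789 and 796 without replicates 1 and 2 of H9 in conditioned medium, 512, 696 and 691 without replicates 1, 2 and 3 of HSF1 in unconditioned medium and 770 and 715 without replicates 2 and 3 of HSF1 in conditioned medium. DUSP6 fell by 2.62 in HSF1 and by 0.71 in H9 (interaction 1.91, SE 0.124, adjusted p = 8.05e-07), and SPRY4 and ETV5 also fell further in HSF1 (-1.91 and -1.95) than in H9 (-0.64 and -0.81). D21S2088E fell in HSF1 (-1.50) and differed by -0.22 in H9, a difference of 1.27. CYP26A1, which degrades retinoic acid, rose by 1.86 in HSF1 and differed by -0.04 in H9, STOM rose by 1.41 against 0.14, DIAPH2 by 1.27 against 0.37, and OPTN fell by 0.95 in H9 against a difference of 0.09 in HSF1. With all 24 arrays in 1 fit the difference between lines was no longer past the threshold for SPRY4 (adjusted p = 0.0568), ETV5 (0.374), STOM (0.126), OPTN (0.117), DIAPH2 (0.819) and CYP26A1 (0.305), and with the mean of all probe sets it was 0.67 for ETV5 and -0.85 for STOM against 1.14 and -1.27. Cholesterol synthesis genes rose in H9 (8 of 19) and not in HSF1, and the difference between lines passed as a list (camera adjusted p = 1.61e-08; adjusted p = 0.0128 with an estimated correlation).

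The feeder effect and the conditioned medium effect, which share no array, correlated across 16518 genes with r = 0.421 and a Spearman rho of 0.493. Taken line by line, the feeder effect of H1, H9 and HSF1 gave r = 0.334, 0.357 and 0.414. Of 1805 genes past the threshold in both comparisons 1568 (86.9%) had the same direction, 299 higher in both and 1269 lower in both, where independent lists of these sizes would share 181.6 and 668.8. With the conditioned medium effect of H9, r was 0.434 and 91.4% of the shared genes had the same direction, 146 higher in both (79.85 in independent lists) and 1082 lower in both (536.5). With that of HSF1, r was 0.294 and 69.0% had the same direction, 714 lower in both (404.7) and 159 higher in both, below the 197.8 of independent lists. The difference between lines in these values was not tested, and H9 includes the 2 arrays with a large ACTB difference. LEFTY1, NODAL, CUZD1 and DUSP6 are examples, and EGR1 (2.27 with feeders, -1.56 with conditioned medium), MT1M (-1.60 and 1.89) and SOX2 (-0.53 and 0.28) moved in opposite directions. With DMSO the interquartile range of the arrays was 2.45 to 2.85 with feeders and 3.08 to 3.22 without. In H9 it was 3.06 to 3.18 with conditioned and 3.19 to 3.30 with unconditioned medium, and in HSF1 3.10 to 3.28 and 3.24 to 3.27. A shift by signal level common to both comparisons could add to the correlation and the shared directions, and stays open. The mean inhibitor effect correlated with the mean feeder effect with r = -0.112 and rho = -0.156, against -0.0292 to 0.0281 in simulations without effects. The covariance was -0.0172 against a simulated -3.27e-05. Line by line r was -0.032, -0.167 and 0.101 in H1, H9 and HSF1 (SD 0.134), and without H9 it was 0.0555, in the opposite direction. The spread between lines was wider than the simulated range and larger than the correlation itself, so no association was shown.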

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

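The test of probe sets without a gene name and the look at which arrays the splits put together were chosen after the data were seen. The response to the inhibitor differed between culture systems for 3 genes: BCHE (-1.853), CTCFL (-3.267) and LINC01234 (-2.136), each with a larger rise in feeder-free cells. Of 100 splits of the arrays, 12 gave at least 3 genes, and the highest other split gave 2595, so chance was not excluded for this count. Splits with far more genes than the real one point to a structure of the samples. In the 2 highest, with 2595 and 2203 genes, both feeder-supported HSF1 arrays, which stood apart, lay on one side, although the median over the 42 splits of that kind was 0. Among the 57 other splits that parted these arrays, and also among the 19 splits that part all pairs, the highest other count was 110. The split with 110 exchanges DMSO and inhibitor in the feeder-free arrays alone, which turns the interaction into the mean inhibitor effect, so it is not a count given by chance. As lists, metallothioneins differed by a median of 1.405, cholesterol synthesis by 0.1475, general pluripotency by -0.1432 and oxidative phosphorylation by -0.07245, and none of these calls held with an estimated correlation (adjusted p = 0.353, 0.919, 0.919 and 0.919).

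The response to conditioned medium differed between H9 and HSF1 for 1281 genes. Of 100 splits 2 gave as many, the real one included, and the highest other split gave 1753. The split with 1753 kept the real groups of HSF1 and set replicates 2 and 3 of H9 in unconditioned medium, which had a large ACTB difference, with replicate 2 in conditioned medium against the other H9 arrays. These splits cannot exclude chance for this count, since exchanging conditioned and unconditioned arrays within a line also removes the effect that both lines share. The difference, H9 minus HSF1, was 1.912 for DUSP6, 1.268 for SPRY4, 1.274 for D21S2088E, 1.141 for ETV5, -1.269 for STOM, -1.045 for OPTN, -0.9016 for DIAPH2 and -1.902 for CYP26A1. Among lists it was 0.2557 for cholesterol synthesis, the call that held with an estimated correlation (adjusted p = 0.0128). It was 0.3258 for FGF and ERK targets, -0.7522 for metallothioneins, 0.2821 for primed-state genes, -0.319 for p53 targets, 0.1286 for general pluripotency and 0.1274 for fatty acid synthesis, with adjusted p = 0.120 to 0.331 with an estimated correlation.

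Probe sets that carry no gene name in the annotation used entered no comparison of genes. Of 7110 tested between culture systems 3061 passed, 1710 higher and 1351 lower with feeders. With the inhibitor 14 passed, and with conditioned medium 305 of 6474 passed, 102 higher and 203 lower.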

How the results depend on the processing

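The fits without the arrays that stand apart, the ACTB covariate, and the list tests without a line or with another block were chosen after seeing the data. Over named genes, 2220 results under an alternative kept their direction and side of the threshold, 126 lost and 40 gained the call and 2 reversed. Only lists past the threshold in the main fit were followed, so a list could not gain a call. Of their results 312 kept the call, 126 lost it and 3 reversed. LDHA between culture systems was 0.0173 with the ACTB covariate, and HK2 with conditioned medium was -0.167 with the mean of its probe sets. Without replicate 2, H9, the cholesterol synthesis list with the inhibitor turned direction (adjusted p when a line was left out 4.6e-08 to 0.578 in feeder-free cells, 2.91e-05 to 0.857 for the mean and 1.85e-06 to 0.605 for the interaction). Except where the alternative fits fewer arrays, the cause was not tested.

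Between culture systems 3125 genes passed after quantile normalization, 11360 with array weights, 11837 with all 24 arrays in 1 fit, 1836 without the line as a block, 351 with the covariate and 358 to 6387 when a line was left out. The covariate ended the calls of HK2, SOX2, HMGCS1, LSS, ALDOC, CER1, EOMES, PRDM1, DUSP6 and MCM5 (adjusted p = 0.0675 to 0.393). With the inhibitor on feeders 1938 passed with weights, 355 with the compared groups alone, 11 with all arrays, 0 without the block and 0 to 0 when a line was left out, in limma, against 132 without the block and 96 to 1089 without a line at an unadjusted p under 0.05. In feeder-free cells the counts were 2388, 3313, 929, 62 without the block, 1683 without the feeder-supported HSF1 arrays, 222 with the covariate and 3 to 421 when a line was left out. For the mean inhibitor effect they were 5888 with weights, 965 with all arrays, 33 without the block, 1372 without the feeder-supported HSF1 arrays, 176 with the covariate and 2 to 500 when a line was left out. The interaction gave 0 in limma with the stricter filter (300 unadjusted), after quantile normalization (373), without the intensity trend (344), without the block (207) and without a line (0 to 0; 139 to 789), 144 with weights and 86 with all arrays. The array weights did not fully converge.

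With conditioned medium in H9 the counts were 4277 with weights, 1142 with the compared groups alone, 176 with all 24 arrays, 653 without replicates 2 and 3 in unconditioned medium, 1469 with the covariate and 1320 to 5286 when an array was left out. In HSF1 they were 4770, 4790 and 329, and 1852 to 2570 when an array was left out. For the mean of both lines all 24 arrays gave 571. The difference between lines gave 3113 with weights, 7 with all arrays, 535 without replicates 2 and 3 of H9 in unconditioned medium and 512 to 3281 when an array was left out. Same-numbered replicates did not deviate together (r = -0.267, 0.132 and -0.102 in H9 and 0.0853, -0.186 and 0.00671 in HSF1), and with the replicate number as a block 1934, 2390, 3248 and 757 genes passed in H9, in HSF1, for the mean and for the difference between lines.

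The correlation of the feeder and conditioned medium effects was 0.376 without the feeder-supported HSF1 arrays, 0.328 without replicates 2 and 3 of H9 in unconditioned medium and 0.371 to 0.430 without a line. That of the inhibitor and feeder effects was -0.150 to 0.0555, reversed without H9. Weakly detected genes are limited by the background of the arrays, and the filter at log2 6 moved the inhibitor interaction count past the 1.5-fold bound and no other count.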

Other observations

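The gene families, the chromosome medians, the parts of the lists set against matched lists, the ratio with the ACTB covariate, the look at which arrays the splits put together, and the interferon test in feeder-free pairs were chosen after the values were seen. Of 25 HOX genes, which pattern the body axis, 17 were higher on feeders and 25 of 25 had a difference above 0 (median 0.62, camera adjusted p = 3.74e-09 over 311 families; adjusted p = 0.689 with an estimated correlation). The median was 0.43, 0.62 and 0.93 in H1, H9 and HSF1, and stayed above 0 under each scaling. Of 68 olfactory receptor genes, whose mean level of 5.90 lies near the detection limit, 26 were higher and 1 lower (median 0.50, adjusted p = 3.71e-09; adjusted p = 0.689 with an estimated correlation).

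In feeder-free cells with the inhibitor, 35 of 44 histone genes lay below 0 and 2 passed (median -0.21, adjusted p = 2.88e-06), and 15 of 15 protocadherin beta genes lay below 0 with 0 passing in limma (median -0.31, adjusted p = 0.000369). The olfactory receptor genes moved the same way in these cells (58 of 68 below 0, median -0.13, adjusted p = 0.0348). All 3 families had adjusted p = 0.995 with an estimated correlation. The histone median was -0.15, -0.21 and -0.27 and the protocadherin median -0.25, -0.45 and -0.33 in H1, H9 and HSF1, and the signs of the histone and protocadherin medians did not flip with the scaling. In HSF1, the median difference between culture systems by chromosome ran from -0.486 on chromosome 13 to 0.597 on chromosome 22, against -0.0831 to 0.11 over all chromosomes in H1 and H9. Across the 22 chromosomes, which are not independent replicates, the medians of HSF1 correlated with those of H1 (r = 0.672) and H9 (r = 0.569), and those of H1 with those of H9 (r = 0.787). The pattern of HSF1 thus recurred in part and at smaller size, as on chromosome 22 (0.107 in H1 and 0.11 in H9) and 13 (-0.0831 and -0.0615). Chromosome 19 (0.413 in HSF1, -0.0314 in H1 and -0.0296 in H9) and 18 (-0.439, 0.00783 and 0.0118) did not share it.

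Genes higher in feeder-supported arrays may in part reflect transcripts of the mouse feeder cells or a difference in RNA quality. Degraded RNA in the feeder-supported arrays would raise the ACTB 3-prime minus 5-prime difference, which was smaller with feeders (-0.443, SD 0.346 over 3 lines). In H1 and H9 the change was -0.462 to 0.02, short of such a rise. In HSF1 with DMSO the 3-prime value was 13.2 with feeders and 13.9 without, and the 5-prime value 13.4 and 13.3. There a lower 3-prime signal made the difference smaller, so it cannot decide on RNA quality in HSF1. The GAPDH 3-prime minus 5-prime difference changed by -0.0545 (SD 0.136), within its spread. Lower quality in the feeder-free arrays stays open. With the ACTB difference as a covariate 351 genes passed, and the median log2 difference of the 2620 higher genes went from 0.71 (median SE 0.205) to 0.47 (median SE 0.264), with a median ratio of 0.667 per gene (quartiles 0.545 and 0.81). The covariate itself differs between culture systems, so this fit cannot part RNA quality from the culture system. Mouse transcripts may also reach part of a gene's probe sets. The other probe sets of 208 genes at least 2-fold higher followed the chosen one more closely than those of 1104 lower genes (ratio 0.385 against 0.279, difference 0.106, 95% interval 0.0335 to 0.158). This cannot decide the point, since a general rise of weakly detected probe sets, taken up below, would move the ratios the same way. Such binding also stays open for single genes, as another probe set differed by -0.08 for CDH11 and -0.25 for PCDH7, against 4.70 and 4.50, although lower genes such as GDA showed such a spread too (-0.25 against -3.39). The human Alu signal differed by -0.127 (SD 0.192), within the spread, and by -0.313 and -0.384 in HSF1, the direction mouse RNA predicts. Mouse RNA that binds part or all of a gene's probe sets thus cannot be told apart from a response of the human cells to feeders.

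Lists higher or lower in feeder-supported arrays may in part reflect a general shift of weakly or strongly detected probe sets. Against random lists matched on level, the fibroblast, naive-state, endoderm and WNT lists had a lowest percentile of 99.5 and the cholesterol, fatty acid and primed-state lists a highest of 0, with and without HSF1. These lists were picked because they lay outside the matched range with all lines, and the fit without HSF1 uses the same H1 and H9 arrays. Their percentiles therefore give no separate test of a general shift. With all lines 4 of the 6 rising and 3 of the 6 falling lists lay outside the central 95%, and without the HSF1 arrays 6 of 6 and 5 of 6, with percentiles of 0.95 for cell cycle, 0.23 for pentose phosphate, 99.97 for mesoderm, 98.1 for trophoblast and 26.27 for glycolysis. By the rules set beforehand the test was undecided for the rising and for the falling lists, so a shift stays open as part of the source. Glycolysis lay inside in both fits, and the other 4 did so with the HSF1 arrays included.

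Of 32 fibroblast genes with a probe set 27 lay above the filter in feeder-free DMSO arrays too and 3 stand in another list. Among the most abundant, the log2 level with and without feeders was 12.5 and 7.88 for S100A6, 12.2 and 10.8 for FN1, 11.8 and 7.12 for CDH11, 11.7 and 10.5 for TAGLN, and 11.3 and 11.2 for SPARC (n = 3 lines each).

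The list of interferon response genes rose with the inhibitor without feeders too, where the lowest of the 3 pair medians was 0.223, which argues against mouse feeder RNA, although the list call in feeder-free pairs alone was lost with an estimated correlation (adjusted p = 0.0656). Over both culture systems, leaving out any 1 line gave an adjusted p of 0.000145 at most with the preset correlation, which argues against a single line. A hypothesis consistent with these tests is that the inhibitor raises interferon response genes in these cells, and effects of the compound apart from its target were not tested.

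With conditioned medium 79.0% of the genes that passed in H9 were lower, or 65.2% without the 2 H9 arrays of unconditioned medium with a large ACTB difference, against 53.3% in HSF1.

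Other splits of the arrays bear on the counts of genes. For the mean of both lines with conditioned medium 1 of 100 splits, the real one, gave as many genes (3982, highest other 882). This share is under 0.05, so a random arrangement of the arrays within each line is unlikely to give the count. Most other splits mix conditioned with unconditioned arrays, which widens their spread and lowers their counts. The gap to 882 therefore does not measure the strength of the effect. For the mean inhibitor effect 3 of 100 gave as many as the real 110. This share cannot exclude chance, since most of these splits break the pairs of the same line and culture system. Among the 19 splits that part all pairs the highest other count was 8, and 19 splits are too few for a share under 0.05. The 2 splits with more genes than the real one, 5775 and 2203, point to a structure of the samples: both put the feeder-supported HSF1 arrays, which stood apart, on one side, and among the 57 other splits that parted these arrays the highest count was 8. Groups of 3 allow 10 splits, too few for a share under 0.05: between culture systems the real count was 6772 and the highest other 0, with the inhibitor on feeders 1 and 1 (2 of 10 splits) and without feeders 145 and 2, and with conditioned medium 2720 and 910 in H9 and 3040 and 0 in HSF1.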
